A study of Homo sapiens with 120 samples.

How the data were processed

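The authors' tables give 1 column per library and 1 row per mature miRNA. Per the submitters' processing notes STAR and the human genome build GRCh38 were used, with versions not given, and the counter, the annotation and the normalization software are not stated. The deposited values are a signal of normalised counts. In each column they are whole multiples of 1 step, within a tolerance of 0.01 of a read, so whole reads were recovered for 100% of them by dividing by that step. The deposited scaling follows median-ratio size factors common to the 48 libraries of a table, so that columns do not sum to the same total, and the ratio of deposited values to such a scaling is 0.976 in every library of experiment 1 and 1.02 in experiment 2. The table named for experiment 3 is byte for byte that of experiment 2, so experiment 3 was left out and nothing was mapped to its libraries.

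Where a mature name has several rows for several loci, the row with the most reads over both tables was kept, which left 2652 names of 2883 rows and set aside 231. A miRNA was tested when it had at least 10 recovered reads in at least 6 libraries of a fit, a limit chosen after the values were seen. No library was left out. The 48 pairs of replicate libraries held 0 identical pairs, and their chi-square per degree of freedom was 8.56 to 1612, so each pair differed by more than counting error. The floor of 3 reads over a group, used where none of its libraries had a read, covers counting error only.

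Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options) on log2(value + 1) of the deposited normalised counts, since the design asked for this with normalised values. A fit of 24 libraries of 1 experiment and fraction had additive terms for cell line and transfection. Cell lines were compared by contrasts of 6 against 6 libraries, and dsRNA with mock by an F test of the dsGFPc and dsGFPd coefficients together, with the direction taken from their mean. Pulldown and total RNA were compared in the 12 parental libraries of an experiment, and the change of their ratio by the interaction of cell line and fraction over 48 libraries. The arm ratio was log2((5p + 1)/(3p + 1)) of hairpins with both arms tested, in total RNA, without the robust option. The response to dsRNA in a knockout minus that in the parental line was tested as an interaction, per fraction. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and the threshold was 0.05.

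Named miRNAs are up to 10 that rose and 10 that fell per comparison, by largest absolute log2 change among those called, with a mean level in the upper part (above the median) of the miRNAs tested and the same sign in each transfection (for dsRNA, in each cell line), plus miR-16-5p and miR-21-5p, which the protocol names as pulldown controls, miR-451a and members of the fixed lists. Outside the rule and chosen after their values were seen are miR-10399-3p and miR-3614-5p in total RNA with dsRNA in experiment 1, miR-6891-5p in pulldown with dsRNA in experiment 2, miR-221-3p and miR-222-3p in total RNA of the PACT and TRBP double knockout, in total RNA of the libraries labelled Ago1ko_Ago2ko and in pulldown of those labelled Ago2ko, these 2 and miR-25-5p between the Ago knockouts, miR-221-3p and miR-222-5p in pulldown with dsRNA in experiment 1, and the miRNAs named for interactions of dsRNA with a cell line. The lists are the miR-17~92 and paralog clusters, the let-7 family, other abundant canonical miRNAs, mirtrons, Drosha-independent miRNAs (miR-320 family and miR-484), Dicer-independent miR-451a, entries overlapping other small RNAs, immune-responsive miRNAs, markers of other cell types, and minor arms (of each hairpin, the arm with the lower mean in parental total RNA of the other experiment). Lists with at least 3 measured members were compared with all other miRNAs by limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 9 lists tested per comparison. Over the list alone, p-values were also adjusted within the list. The comparisons, tests, lists and the rule for named miRNAs were fixed before the data were examined, except the interactions of dsRNA with a cell line, which were added later.

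Alternatives were a log2 change of at least 1, quantile normalization, columns scaled to the same sum, no low-count filter, a pseudocount of 0.1 or 10 (0.5 or 10 for arms), replicate number as a block, mock libraries only, only the 2 cell lines compared, a mean of at least 50 in both arms, pulldown in place of total RNA for arms, scaling on the entries overlapping other small RNAs for Dicer, and leaving out each library and each replicate number. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood, TMM factors) and DESeq2 1.42.0 on the recovered reads, all rows of repeated loci, fits without the Dicer knockout libraries, and the pulldown to total ratios with the labels of the 2 Ago knockouts exchanged in pulldown, and mock libraries only for the arm ratios. Each test was also tested on simulated reads, drawn from a negative binomial with the levels and edgeR dispersions of its libraries, in which 100 miRNAs were changed 2-fold and 100 4-fold, up or down (50 arms in all for the arm ratios). Over the 5 comparisons of experiment 1 in total RNA 93 to 98% of 4-fold and 74 to 81% of 2-fold changes were recovered, and over those of experiment 2 in pulldown 18 to 38% and 2 to 6%. Locations are those of the miRNA genes in GRCh38.p14, matched by name for 215 of 221 named miRNAs, with the genes that span them. The gene table gives spans without exons.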

Results

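Small RNA was sequenced from HEK293T cells, a human embryonic kidney line, that carry a knockout of PKR, the kinase activated by double-stranded RNA (dsRNA). The labels of experiment 1 name the PKR-knockout parental line and derived lines without PACT, without TRBP and without both, and those of experiment 2 name the parental line and lines without Ago2, without Ago1 and Ago2, and without Dicer. PACT and TRBP are dsRNA-binding partners of Dicer, the enzyme that makes mature miRNAs from hairpin precursors, and Ago proteins bind the mature strand. Each line was transfected with no dsRNA (mock) or with 1 of 2 long dsRNAs labelled dsGFPc and dsGFPd, and libraries were made from total RNA and from RNA copurified with Ago proteins (Ago pulldown), with 2 libraries in each of these groups. This makes 48 libraries per experiment and 96 in all, with 6 per cell line and fraction and 8 per transfection and fraction. Experiment 3, with 24 libraries labelled with 11 dsRNAs and mock, was not used here.

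The values are normalised read counts per mature miRNA, from which whole reads were recovered. Experiment 1 had 406531 to 1104630 miRNA reads per library in total RNA and 2457547 to 13457930 in Ago pulldown. In experiment 2 the libraries other than Dicer knockout had 910155 to 7167395, whereas the Dicer knockout had 39916 to 180343 in total RNA and 47006 to 593510 in pulldown. A single read was worth 4.86 to 32.5 normalised counts in the Dicer knockout and 0.088 to 0.60 in the rest of experiment 2. A miRNA is said to have risen or fallen only at a limma adjusted p under 0.05, and fold changes are differences of log2(value + 1). Near 0 this understates a change where a read is worth less than the added 1. In the Dicer knockout a miRNA without a read is set far below the value of 1 read, so its fall can be overstated. Levels are means ± SD over 6 libraries unless another number is given. The p-values measure the spread between these libraries, since the labels do not say whether the 2 libraries of a group came from separate cultures. The mRNAs of the deleted genes are not measured by small RNA libraries, so the cell lines are known here by their labels alone. All libraries of a knockout bear the same line label. An effect of the knockout thus cannot be told apart from other differences between the lines.

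**Figure D1:**
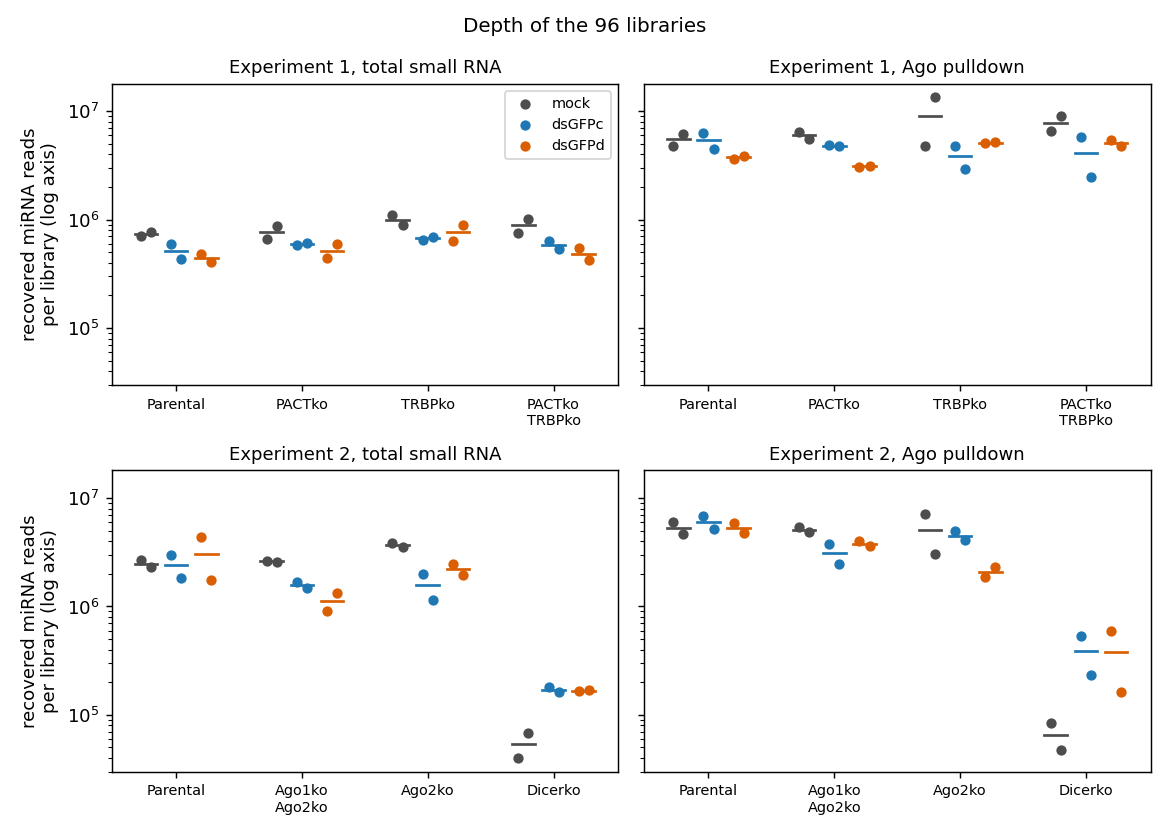
Recovered miRNA reads per library (log axis) by cell line and transfection, with a point per library and a bar at the mean of each group of 2. The Dicer knockout libraries of experiment 2 hold 39916 to 180343 reads in total small RNA, against at least 910155 in the other lines of that experiment.

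PACT loss was compared with the parental line to ask which miRNAs need this Dicer partner. Few miRNAs changed in total RNA. Of 422 miRNAs tested, 2 rose and 4 fell. The p53 target miR-34a-5p (MIR34A, GRCh38.p14 chromosome 1, 9151668 to 9151777, within the span of MIR34AHG) rose from 247 ± 127 to 495 ± 167, a log2 change of 1.07, and miR-31-5p rose by 0.63. The arms of MIR181C fell, miR-181c-5p by 0.64 and miR-181c-3p by 0.61, as did miR-221-5p by 0.39 and miR-10b-5p by 0.23. The calls of miR-31-5p and miR-181c-5p were made in all 12 fits that left out 1 library, and that of miR-34a-5p in all but 4. The direction of the total rested on scaling, with 6 higher and 3 lower when every library had the same sum and 2 of each after quantile normalization. Only 2 calls were left without parental dsGFPd replicate 1, without PACTko mock replicate 2 or without PACTko dsGFPc replicate 2. In pulldown limma called 0 of 897 miRNAs (31 at an unadjusted p under 0.05), edgeR 0 and DESeq2 3. The let-7 family had a pulldown median of −0.28, with an adjusted p of 0.0011 by limma's camera at a preset correlation of 0.01 and 0.42 with an estimated correlation. On simulated reads with 4-fold changes put into 100 miRNAs the same test recovered 97% of them in total RNA and 71% in pulldown, against 81% and 30% of 2-fold changes.

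TRBP loss was compared with the parental line for the same question. The miR-221/222 cluster fell most. In total RNA miR-221-3p fell from 16770 ± 922 to 1913 ± 219, a log2 change of −3.14 ± 0.07 (SE), with a limma adjusted p of 2.84e-25. Its cluster neighbour miR-222-3p fell from 30010 ± 8792 to 4120 ± 1177, a change of −2.86, and the passenger arms miR-221-5p and miR-222-5p fell by 2.74 and 3.23. Both hairpins lie on chromosome X within MIR222HG (MIR221 at 45746157 to 45746266, MIR222 at 45747015 to 45747124). The p53 target miR-34a-5p fell from 247 ± 127 to 61.2 ± 39.2. Smaller decreases were those of miR-1275 (−0.82), miR-424-3p (−0.79), miR-328-3p (−0.76), miR-576-5p (−0.79) and miR-3651 (−1.09), of which the last 2 were not called in 4 and 5 of the 12 fits without 1 library. The largest increase among the named miRNAs was that of miR-548f-3p, from 356 ± 79.6 to 691 ± 124, or 0.97. It was followed by miR-1468-5p (0.88), miR-7706 (0.74), miR-454-5p (0.72), miR-126-5p (0.71), miR-1307-3p (0.67), miR-129-5p (0.66) and miR-500a-3p (0.64). In all, 40 miRNAs rose and 46 fell of 422, and 50 rose and 39 fell after quantile normalization.

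The let-7 family went both ways without TRBP. Of its 9 members 4 rose, with let-7i-5p at 0.54, miR-98-5p at 0.46, let-7f-5p at 0.29 and let-7c-5p at 0.23, and 2 fell, with let-7e-5p at −0.50 and let-7b-5p at −0.37. The call of let-7c-5p was lost in 8 of 12 fits without 1 library. The pulldown control miR-16-5p rose by 0.16, a call lost in 5 of those fits. In Ago pulldown 12 miRNAs rose and 24 fell of 897, or 22 and 19 when every library had the same sum. The same cluster led there, with miR-221-3p falling from 6860 ± 2084 to 805 ± 138, miR-222-3p by 2.41, miR-222-5p by 2.55 and miR-221-5p by 2.07. miR-34a-5p fell by 2.55, miR-1293 by 2.11, miR-3144-3p by 2.04 and the muscle marker miR-1-3p by 1.18. Increases in pulldown were led by miR-548f-3p (1.45), miR-2110 (0.96), miR-935 (0.95), miR-454-5p (0.82) and miR-7706 (0.72). No fixed list was called by camera in either fraction.

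Loss of both PACT and TRBP was compared with the parental line to ask what remains without either partner. The let-7 family fell, and miR-221-3p and miR-222-3p were not called. In total RNA 8 of the 9 let-7 members fell (8 also when adjusted over the list alone), with a median log2 change of −0.46. The limma camera test gave an adjusted p of 8.79e-11, and 0.0465 with an estimated correlation. The largest was let-7b-5p (MIRLET7B, chromosome 22, 46113686 to 46113768, within MIRLET7BHG), from 883 ± 91.4 to 389 ± 63.5, and let-7e-5p (MIRLET7E, chromosome 19, 51692786 to 51692864, within SPACA6) went from 6217 ± 602 to 3644 ± 426. miR-204-5p (MIR204, chromosome 9, 70809975 to 70810084, within TRPM3) fell from 230 ± 41.6 to 87.3 ± 17.2, a change of −1.39. Other decreases were miR-324-5p (−0.95), miR-218-5p (−0.85), miR-151a-3p (−0.67), miR-181c-5p (−0.63), miR-342-3p (−0.57) and miR-1291 (−0.55). miR-221-3p stood at 14600 ± 1384 against 16770 ± 922, a change of −0.20 that was not called, and miR-222-3p at 28770 ± 7935 against 30010 ± 8792. These 2 were named after their values were seen.

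Most measured members of the Drosha-independent list (the miR-320 family and miR-484) rose with the loss of both partners. Of its 4 measured members 3 rose (3 adjusted over the list alone), including miR-320a-3p (MIR320A, chromosome 8, 22244966 to 22245037) from 9641 ± 1213 to 16380 ± 2704 and miR-320b by 0.67, but not miR-484 (0.06). The limma camera adjusted p of the list was 0.000539, and 0.0465 with an estimated correlation. miR-34a-5p rose to 522 ± 164, a change of 1.17, and miR-486-5p from 187 ± 37.2 to 417 ± 90.4. Further increases were miR-129-5p (0.88), miR-598-3p (0.78), miR-31-5p (0.57), miR-152-3p (0.55), miR-221-5p (0.49) and miR-92a-1-5p (0.44). In all 23 miRNAs rose and 36 fell of 422, and 49 rose and 28 fell when every library had the same sum, which moved the median of all miRNAs from −0.02 to 0.10. The medians of let-7 and of the Drosha-independent list kept their sign under that scaling and under quantile normalization.

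In Ago pulldown of the same lines let-7 again had the lower level. Of its 9 members 5 fell (7 adjusted over the list alone), with limma camera adjusted p of 9.84e-10 and 0.0181 with an estimated correlation. let-7b-5p fell from 1798 ± 604 to 598 ± 148, or by 1.55, let-7e-5p by 1.16, let-7c-5p by 0.81, let-7a-5p by 0.62 and let-7g-5p by 0.56. miR-204-5p fell from 824 ± 233 to 165 ± 45.8, a change of −2.32. miR-30b-3p fell by 1.12, miR-4446-3p by 1.19 and miR-4661-5p by 1.17, and miR-3159 rose by 1.05, miR-320b by 0.77, miR-192-5p by 0.64 and miR-181a-5p by 0.58. The Drosha-independent list had an adjusted p of 0.0206 and 0.252 with an estimated correlation, and the immune-responsive list 0.0113 and 0.105, both by limma's camera. In all 6 rose and 15 fell of 897, with 12 and 8 at the same sum and 7 and 8 after quantile normalization. Over the 12 alternatives other than leaving out libraries the count was 5 to 34. This count rested on single libraries. It was 5 without parental dsGFPc replicate 2 or parental dsGFPd replicate 2, 6 without double knockout mock replicate 1 or dsGFPc replicate 1, 9 without double knockout mock replicate 2, dsGFPd replicate 1 or parental mock replicate 2, and 12 without double knockout dsGFPc replicate 2. The calls of let-7b-5p, let-7e-5p and miR-204-5p did not depend on any of the 12 libraries.

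The double knockout was compared with the TRBP knockout to test what the loss of PACT adds when TRBP is gone. The miR-221/222 cluster, miR-34a-5p and let-7 separated these lines. Both lines lack TRBP by their labels. The falls of miR-221-3p, miR-222-3p and miR-34a-5p in the TRBP knockout therefore cannot be assigned to TRBP loss alone. In total RNA miR-221-3p rose from 1913 ± 219 to 14600 ± 1384, a change of 2.93, and miR-222-3p by 2.81, miR-221-5p by 3.23, miR-222-5p by 3.60 and miR-34a-5p by 3.21. miR-486-5p rose by 1.86 and miR-598-3p by 1.05. All 9 let-7 members fell (9 adjusted over the list alone), with miR-98-5p at −1.05 and let-7i-5p at −0.94, and the limma camera adjusted p was 3.99e-07, or 0.179 with an estimated correlation. miR-204-5p fell by 1.17 and miR-548f-3p by 1.11. Of the Drosha-independent list 3 of 4 rose (adjusted p 0.0166 by limma's camera, 0.179 with an estimated correlation), and of the 18 other abundant canonical miRNAs 3 rose and 9 fell (0.0441, and 0.458). In all 75 rose and 76 fell of 422, and 91 and 50 at the same sum. In pulldown 36 rose and 60 fell of 897, led by miR-34a-5p (3.51), miR-221-3p (2.69), miR-204-5p (−1.53) and miR-548f-3p (−1.38). There 7 of 9 let-7 members fell, with adjusted p of 4.78e-06 by limma's camera and 0.109 with an estimated correlation.

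**Figure D2:**
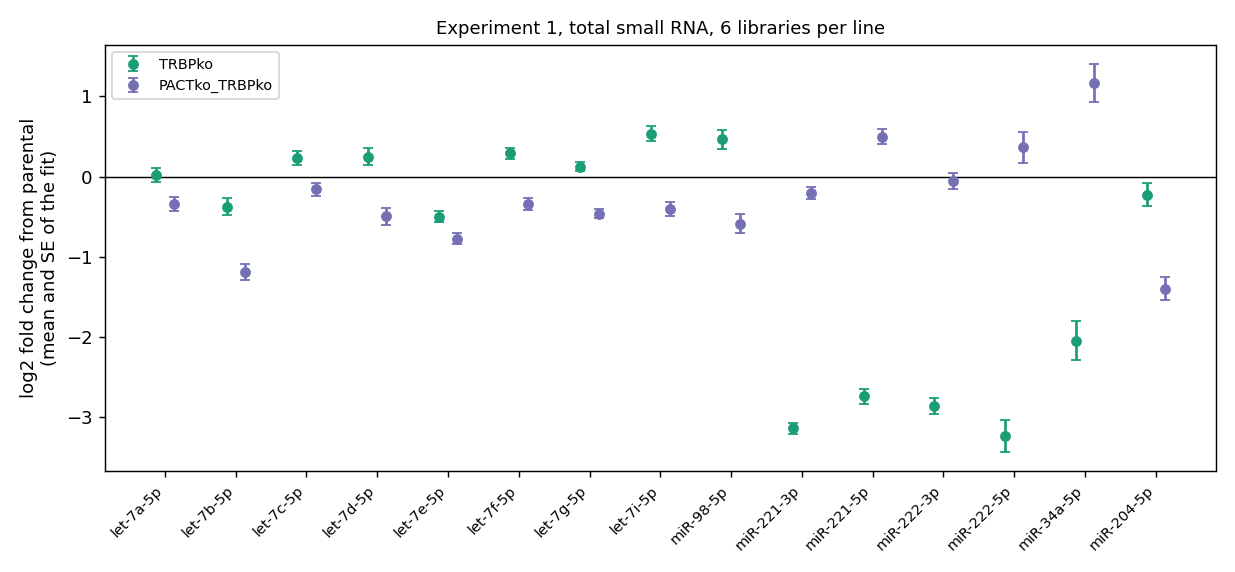
Log2 fold change from the parental line in total small RNA of experiment 1, with points at the fitted change and bars of 1 SE, for the TRBP knockout and the PACT and TRBP double knockout (6 libraries each). miR-221-3p is at −3.14 without TRBP and −0.20 without both proteins, and let-7b-5p is at −0.37 and −1.19, with the same signs of the double knockout's let-7 median under each scaling tried.

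The ratio of Ago pulldown to total RNA was compared between lines to ask whether loading into Ago changed beyond the level. In experiment 1 limma called 0 of 915 miRNAs for PACT, TRBP and both (33, 38 and 63 at an unadjusted p under 0.05), edgeR called 0 for each and DESeq2 1, 0 and 0. The self-test of these ratios recovered 37, 43 and 39% of 4-fold and 30, 13 and 24% of 2-fold changes, so many changes of that size could be missed. The 5p to 3p arm ratio of 101 hairpins was compared to ask whether strand choice moved. It was called for 0 hairpins without PACT (2 at an unadjusted p under 0.05, by limma, the tool run) and for miR-126 and miR-221 without TRBP and without both. The miR-126 ratio rose by 0.74 and 0.76 and that of miR-221 by 0.40 and 0.70 in those lines. The call of miR-221 without both proteins held in every fit without 1 library, but those of miR-126 and miR-221 without TRBP were lost in 11 and 10 of 12 fits and that of miR-126 without both in 6.

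Ago pulldown was compared with total RNA in parental cells to ask which annotated miRNAs are bound by Ago. Several abundant entries of the miRNA annotation were almost absent from Ago. In experiment 1 miR-1291 (MIR1291, chromosome 12, 48654444 to 48654530, within KANSL2) had 23350 ± 5814 in total RNA and 0.337 ± 0.477 in pulldown, and miR-10395-3p had 35390 ± 7060 and 27.5 ± 47.97. miR-7974 fell by 8.11, miR-10395-5p by 7.31, miR-3168 by 4.71 and miR-1275 by 4.399. Of the list of entries overlapping other small RNAs miR-1291, miR-3651 (−8.28) and miR-1248 (−6.17) fell and 3 of 6 rose. Other miRNAs that fell were miR-98-5p at −2.41, miR-671-5p at −2.33, miR-181c-5p at −2.22 and miR-96-5p at −2.12. The pulldown controls miR-16-5p and miR-21-5p were at −0.66 and −0.61, from 6266 ± 231 to 4033 ± 765 for miR-16-5p.

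The named miRNAs raised most in pulldown included the minor arms miR-25-5p, miR-1306-5p, miR-193b-5p, miR-92b-5p, miR-149-3p and miR-505-5p. miR-25-5p (MIR25, chromosome 7, 100093560 to 100093643, within MCM7) rose from 307 ± 111 to 4258 ± 1540, or by 3.79, miR-1306-5p by 3.94, miR-197-3p by 3.54, miR-1249-3p by 3.51, miR-193b-5p by 3.16, miR-92b-5p by 3.11, miR-149-3p by 3.08, miR-505-5p by 2.93 and miR-483-5p by 2.90. All 6 measured mirtrons, which splicing makes in place of Drosha, rose, miR-877-5p by 2.37 (limma camera adjusted p 0.052). Of the minor arms 53 rose and 34 fell, with a median of 0.37, or 37 and 44 with a median of −0.02 after quantile normalization. Of the miR-17~92 clusters 1 rose and 6 fell of 10 (0.0308, and 0.501 with an estimated correlation) and of the other abundant miRNAs 2 rose and 11 fell of 18 (0.0221, and 0.501), both by limma's camera. In all 231 rose and 132 fell of 556, around a median of 0.45, and 164 and 165 after quantile normalization, which moved the median to 0.15. The count was 241 without parental mock pulldown replicate 1 or parental dsGFPc pulldown replicate 2. In experiment 2, 141 rose and 51 fell of 645 (98 and 70 after quantile normalization, 111 and 64 at the same sum, with medians of 0.31, −0.09 and 0.12). miR-25-5p rose there by 2.87, miR-197-3p by 3.19, miR-483-5p by 4.61 and miR-92b-5p by 3.09, and miR-7974 fell by 8.43, miR-10395-5p by 7.23 and miR-10395-3p by 6.92. Of 5 mirtrons 4 rose (5 adjusted over the list alone), and of the miR-17~92 clusters 4 of 10 fell, each with a limma camera adjusted p of 0.0499 and 0.642 with an estimated correlation.

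Long dsRNA was compared with mock over the 4 lines of experiment 1 to ask whether it changes the cells' own miRNAs. It raised a few miRNAs encoded within genes that interferon induces, and miR-155-5p. In pulldown (8 libraries each) miR-10399-3p (MIR10399, chromosome 7, 139044100 to 139044157, within the antiviral gene ZC3HAV1) was at 3.33 ± 2.40 in mock, 518 ± 191 with dsGFPc and 478 ± 98.4 with dsGFPd, a mean log2 change of 6.99. miR-3614-5p (MIR3614, chromosome 17, 56891270 to 56891355, within TRIM25) rose from 0.205 ± 0.251 to 46.5 ± 13.1 and 64.4 ± 15.01, miR-6891-5p (MIR6891, chromosome 6, 31355224 to 31355316, within HLA-B) from 1.19 ± 0.853 to 32.8 ± 19.4 and 45.4 ± 29.6, and miR-10399-5p by 4.72. The inflammatory miR-155-5p (MIR155, chromosome 21, 25573980 to 25574044, within MIR155HG) rose from 1.35 ± 1.88 to 31.9 ± 23.8 and 25.4 ± 19.2, or by 3.57. Abundant miRNAs that rose were miR-27b-3p, from 1338 ± 248 to 4221 ± 986 and 4308 ± 897, and miR-296-3p, from 838 ± 224 to 2479 ± 587 and 2485 ± 831. They were joined by miR-33b-5p (1.85), miR-3663-3p (1.47) and miR-3200-3p (1.27).

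Of the miR-221/222 cluster 2 members fell with dsRNA. miR-222-3p fell from 82570 ± 45170 to 41340 ± 24530 and 39430 ± 20900, or by 0.99, and miR-221-5p from 1104 ± 541 to 469 ± 232 and 465 ± 240. miR-221-3p (0.03) was not called, nor was miR-222-5p at −1.115, with a limma adjusted p of 0.0535 that was 6.66e-05 to 0.175 over 36 alternatives and under 0.05 in 14 of them. miR-1260b fell by 1.33, miR-1910-5p by 1.02, miR-766-3p by 0.96 and the mirtron miR-1226-3p by 0.9985. Of the immune-responsive list 2 of 10 rose (2 adjusted over the list alone), miR-155-5p and miR-212-3p, with a limma camera adjusted p of 0.00207 and 0.0825 with an estimated correlation. Of the miR-17~92 clusters 3 of 11 rose (4 adjusted over the list alone; 0.0118, and 0.354), and of the other abundant miRNAs 5 of 18 (0.00207, and 0.321), both by limma's camera. In all 50 rose and 51 fell of 897 around a median of −0.12, with 53 and 35 after quantile normalization. The count was 63 without parental mock replicate 1, and the calls of miR-1226-3p and miR-4749-5p (−1.003) were lost without that library.

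**Figure D3:**
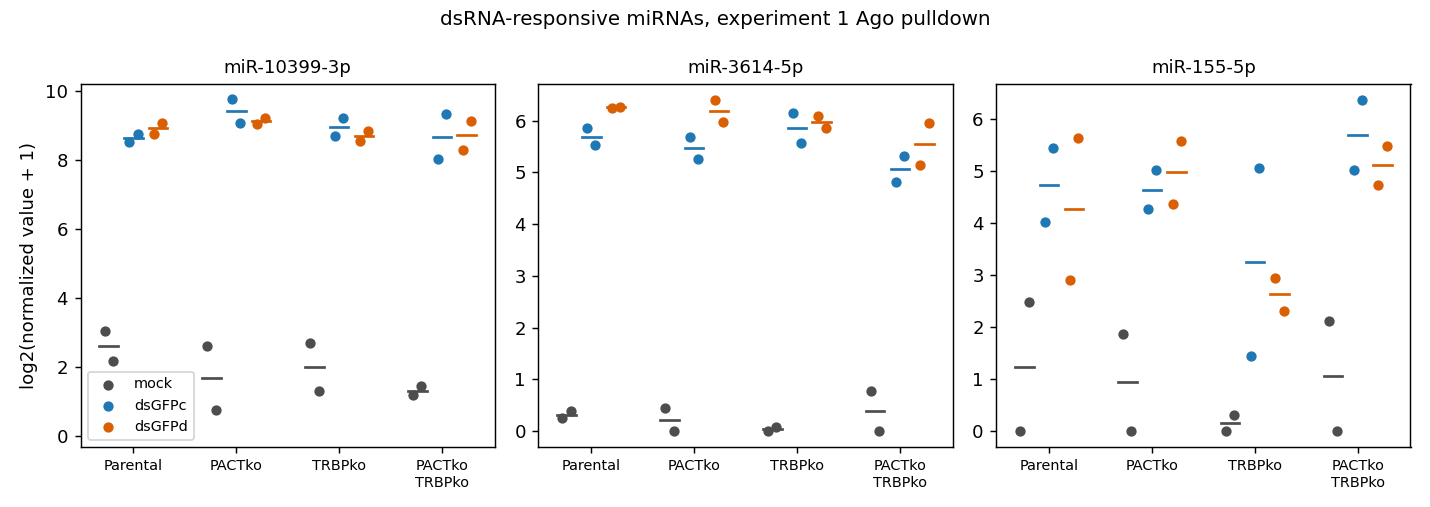
Level of miR-10399-3p, miR-3614-5p and miR-155-5p as log2(normalised value + 1) in Ago pulldown of experiment 1, by cell line and transfection, with a point per library and a bar at the mean of each group of 2. miR-10399-3p averages 3.33 in mock, 518 with dsGFPc and 478 with dsGFPd over the 4 lines.

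In total RNA of experiment 1, 50 miRNAs rose and 32 fell of 422 (43 and 49 at the same sum). miR-10399-3p went from 0.534 ± 1.14 to 155 ± 73.7 with dsGFPc and 247 ± 84.6 with dsGFPd, miR-3614-5p rose by 5.31 and miR-155-5p by 1.95. Entries overlapping other small RNAs rose in part, miR-1248 (MIR1248, chromosome 3, 186786672 to 186786777, within EIF4A2) from 14 ± 4.42 to 135 ± 108 and 157 ± 111 and miR-3651 by 2.07, 2 of 5 in that list, with a limma camera adjusted p of 0.0125 and 0.259 with an estimated correlation. miR-27b-3p rose by 1.05, miR-449c-5p by 1.03, miR-18a-3p by 0.80, miR-296-3p by 0.79, miR-424-3p by 0.72 and miR-92b-3p by 0.65. miR-222-3p fell by 0.63, miR-454-5p by 0.57, miR-340-3p by 0.53 and miR-7706 by 0.52. The miR-17~92 clusters had 4 of 10 members up (0.0156 by limma's camera, 0.266 with an estimated correlation), and 3 of these were compared between the 2 dsRNAs. miR-20a-5p was at 3833 ± 342 in mock, 4182 ± 614 with dsGFPc and 7782 ± 1050 with dsGFPd, and miR-93-5p at 7387 ± 852, 7594 ± 471 and 13650 ± 1557. The dsGFPd libraries exceeded the dsGFPc libraries by 0.90 log2 for miR-20a-5p, 0.84 for miR-93-5p and 0.60 for miR-17-5p, each with p = 0.00016 in an exact two-sided permutation test of 8 against 8 libraries (0.00031 adjusted over 6 tests), the smallest p it can give. The same test in pulldown gave 0.28, 0.18 and 0.15 log2 with p of 0.161, 0.226 and 0.196 (exact, two-sided; adjusted p 0.226 for each). These tests were chosen after the values were seen, and the adjustment does not cover that choice. Libraries were permuted across the cell lines without regard to line. The difference between the 2 dsRNAs was not tested in experiment 2.

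**Figure D4:**
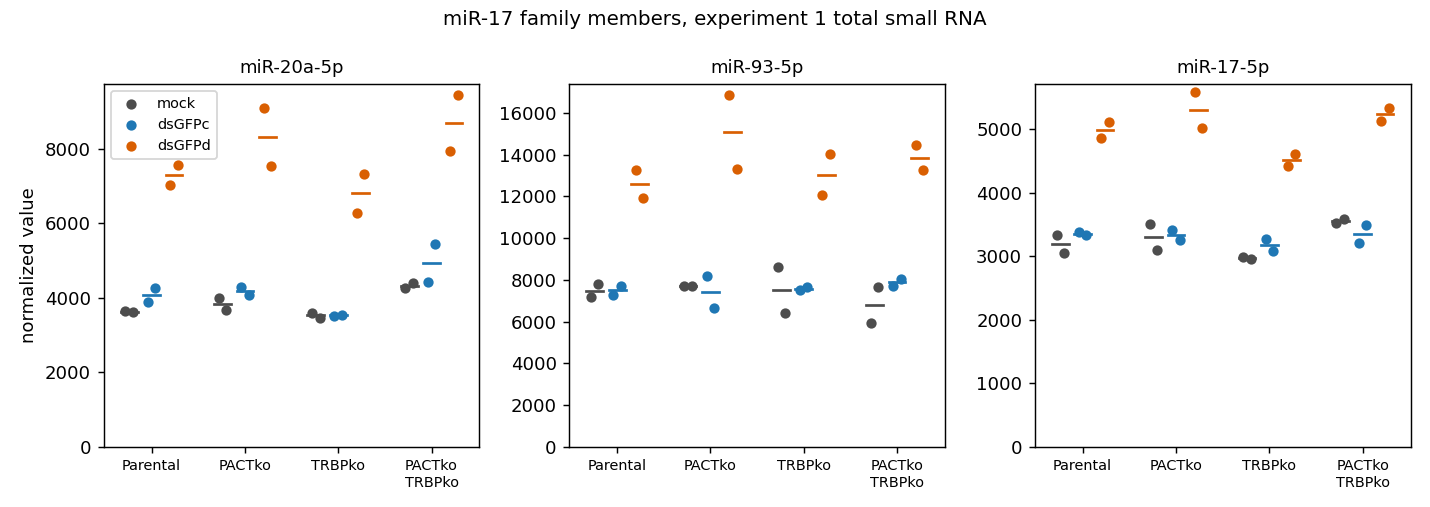
Normalised value of miR-20a-5p, miR-93-5p and miR-17-5p in total small RNA of experiment 1 by cell line and transfection, with a point per library and a bar at the mean of each group of 2. For miR-20a-5p the 8 dsGFPd libraries lie between 6274 and 9455 and the 8 dsGFPc libraries between 3518 and 5452.

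The response to dsRNA was compared between each knockout and the parental line as an interaction. In experiment 1 limma called 0 miRNAs for PACT and TRBP in total RNA (12 and 18 at an unadjusted p under 0.05) and in pulldown (75 and 91), and for both proteins 0 in total RNA (11) and 1 in pulldown, miR-8072 at 3.13 (adjusted p 0.025, 78 unadjusted). edgeR and DESeq2 were not run for these interactions.

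The libraries labelled Ago2ko were compared with the parental line to ask which miRNAs depend on Ago2, the Ago protein that cleaves its targets. Of the miRNAs named here for total RNA the minor arms miR-25-5p, miR-21-3p, miR-27b-5p and miR-27a-5p rose and miR-221-5p and miR-222-5p fell. miR-25-5p rose from 275 ± 100 to 3486 ± 946, miR-21-3p from 101 ± 47.4 to 960 ± 244, miR-27b-5p by 3.81, miR-32-3p by 3.03, miR-92a-1-5p by 2.57, miR-27a-5p by 2.44, miR-424-3p by 2.38 and miR-7-1-3p by 2.18. miR-221-3p fell from 16210 ± 7160 to 626 ± 86.2, or by 4.59, miR-222-3p by 4.36, miR-222-5p by 4.08, miR-221-5p by 3.64, miR-17-5p by 1.90 and miR-148a-3p by 1.21. Of the fixed list of 159 minor arms 13 rose and 2 fell (14 and 2 adjusted over the list alone), with adjusted p of 0.0051 by limma's camera and 0.243 with an estimated correlation, and of the miR-17~92 clusters 2 of 10 fell (3 adjusted over the list alone; 0.0045, and 0.0435 with an estimated correlation). In all 26 rose and 8 fell of 644, and 40 and 22 after quantile normalization. This count of 34 was 122 without the Dicer knockout libraries, 113 with only the 2 lines, and 92 by DESeq2 and 52 by edgeR. The arm ratio was called for 10 of 153 hairpins, 3 toward 5p and 7 toward 3p, among them miR-25 (3.55), miR-27b (3.64) and miR-21 (−2.78). That count was 48 in pulldown libraries in place of total RNA, 4 in mock libraries alone, 59 without the Dicer knockout libraries, 6 without parental mock replicate 1 or Ago2ko mock replicate 2 and 5 without parental dsGFPc replicate 1 or Ago2ko dsGFPd replicate 1.

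The libraries labelled Ago1ko_Ago2ko had more calls in total RNA, 147 against 34, with larger increases of miR-21-3p, miR-25-5p and miR-27b-5p and smaller decreases of miR-221-3p (−2.11) and miR-222-3p (−1.90). miR-21-3p (MIR21, chromosome 17, 59841266 to 59841337, within VMP1) rose from 101 ± 47.4 to 9649 ± 1526, or by 6.66, miR-25-5p to 17150 ± 1916, miR-92a-1-5p from 2320 ± 728 to 88540 ± 27030, miR-29b-1-5p by 6.42, miR-19a-5p by 6.32, miR-19b-1-5p by 5.65, miR-27b-5p by 5.52, miR-195-3p by 5.43, miR-27a-5p by 5.40 and miR-16-2-3p by 5.02. miR-548l fell by 3.48, miR-589-5p by 3.44, miR-548k by 3.10, miR-660-5p by 2.69, miR-148b-3p by 2.63, miR-340-5p by 2.61, miR-99b-5p by 2.59, miR-18a-5p by 2.59 and miR-17-5p by 2.51. Of 159 minor arms 47 rose and 1 fell (48 and 2 adjusted over the list alone; limma camera adjusted p 0.00028, and 0.0676 with an estimated correlation). Of the let-7 family 7 of 9 rose (7 adjusted over the list alone; 0.0053, and 0.188), of the miR-17~92 clusters 3 of 10 fell (0.0053, and 0.0676) and of the other abundant miRNAs 1 rose and 4 fell of 18 (0.0018, and 0.0676), by the same limma test. In all 99 rose and 48 fell of 644, but 96 and 123 after quantile normalization, which moved the median from 0.04 to −0.17, and 288 were called without the Dicer knockout libraries. The arm ratio was called for 22 hairpins toward 5p and 41 toward 3p of 153, led by miR-19a (6.38), miR-27b (6.26) and miR-25 (5.57) and by miR-21 (−6.03). That count of 63 was 38 with a mean of at least 50 in both arms, 34 in mock libraries alone and 3 in pulldown libraries in place of total RNA. The self-test of this arm comparison recovered 20% of 4-fold and 0% of 2-fold changes, and unchanged hairpins made up 16.7% of its 6 calls.

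In Ago pulldown it was the libraries labelled Ago2ko that had more calls, 183 against 21. Against the parental line 78 miRNAs rose and 105 fell of 762, around a median of −0.38, with 51 and 175 at the same sum (median −0.84). miR-25-5p rose from 1960 ± 609 to 235600 ± 72260, miR-21-3p from 57.7 ± 35.9 to 5358 ± 2718, miR-92a-1-5p from 10960 ± 5232 to 309600 ± 104100, miR-19a-5p by 7.68, miR-195-3p by 6.17, miR-27a-5p by 6.16 and miR-27b-5p by 5.86. miR-590-3p fell by 4.57, miR-548l by 4.32, miR-6741-3p by 4.13, miR-935 by 3.59, miR-454-3p by 3.31, miR-598-3p by 3.23 and miR-340-5p by 3.08, whereas miR-221-3p (−2.50) and miR-222-3p (−2.12) fell less than in the libraries labelled Ago1ko_Ago2ko. Minor arms had 35 up and 17 down of 200 (limma camera adjusted p 0.0085, and 0.227 with an estimated correlation), or 25 up and 30 down at the same sum. In the libraries labelled Ago1ko_Ago2ko 13 rose and 8 fell, or 4 and 8 at the same sum. miR-25-5p rose there to 58180 ± 25270, miR-21-3p by 3.11, miR-27b-5p by 3.80 and miR-424-3p by 2.60, and miR-221-3p fell by 4.77, miR-222-3p by 4.48, miR-222-5p by 5.27, miR-221-5p by 4.13 and miR-17-5p by 2.02. That count of 21 was 53 without the Dicer knockout libraries, 10 without Ago1ko_Ago2ko dsGFPd replicate 2, 11 without parental mock replicate 1 or Ago1ko_Ago2ko dsGFPc replicate 1, 12 without parental mock replicate 2 and 13 without Ago1ko_Ago2ko dsGFPc replicate 2.

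The 2 Ago knockouts were then compared with each other to test what Ago1 loss adds. Their differences had opposite signs in the 2 fractions. From Ago2ko to Ago1ko_Ago2ko miR-21-3p rose by 3.36 in total RNA and fell by 3.44 in pulldown, miR-221-3p by 2.48 and −2.27, miR-222-3p by 2.46 and −2.36, miR-25-5p by 2.33 and −2.08 and miR-19a-5p by 4.38 and −4.39, whereas miR-10b-5p fell by 1.48 in total RNA and rose by 1.41 in pulldown. Of 30 miRNAs called in both fractions, all 30 had opposite signs. In total RNA 47 rose and 19 fell of 644 (53 and 60 after quantile normalization, 32 and 24 at the same sum), and in pulldown 22 rose and 32 fell of 762 (82 and 19 at the same sum, with medians of 0.31 and 0.75). Without the Dicer knockout libraries 217 and 162 were called. The pulldown count was 34 without Ago1ko_Ago2ko mock replicate 1 and 30 without Ago2ko dsGFPd replicate 1. In total RNA 16 minor arms rose of 159 (limma camera adjusted p 0.0021, and 0.136 with an estimated correlation) and 3 of 9 let-7 members (0.00092, and 0.136). In pulldown 1 let-7 member of 9 fell (0.0189, and 0.304) around a median of −0.60, which became 0.04 at the same sum. The changes of the pulldown to total ratio were called for 8 up and 1 down in Ago2ko (2 and 33 at the same sum, 12 and 9 after quantile normalization) and 4 up and 15 down in Ago1ko_Ago2ko of 900 (2 and 19 at the same sum). Those of miR-21-3p were 3.25 and −3.54 and those of miR-221-3p 2.09 and −2.66. The Ago1ko_Ago2ko count was 12 without Ago1ko_Ago2ko dsGFPd total replicate 2 or without Ago1ko_Ago2ko mock pulldown replicate 2. Without the Dicer knockout libraries the 2 counts were 100 and 96. With the labels of the Ago knockouts exchanged in pulldown, which was tried after the values were seen, limma called 0 and 1 (18 and 58 at an unadjusted p under 0.05), edgeR 0 and 0 and DESeq2 0 and 1.

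**Figure D5:**
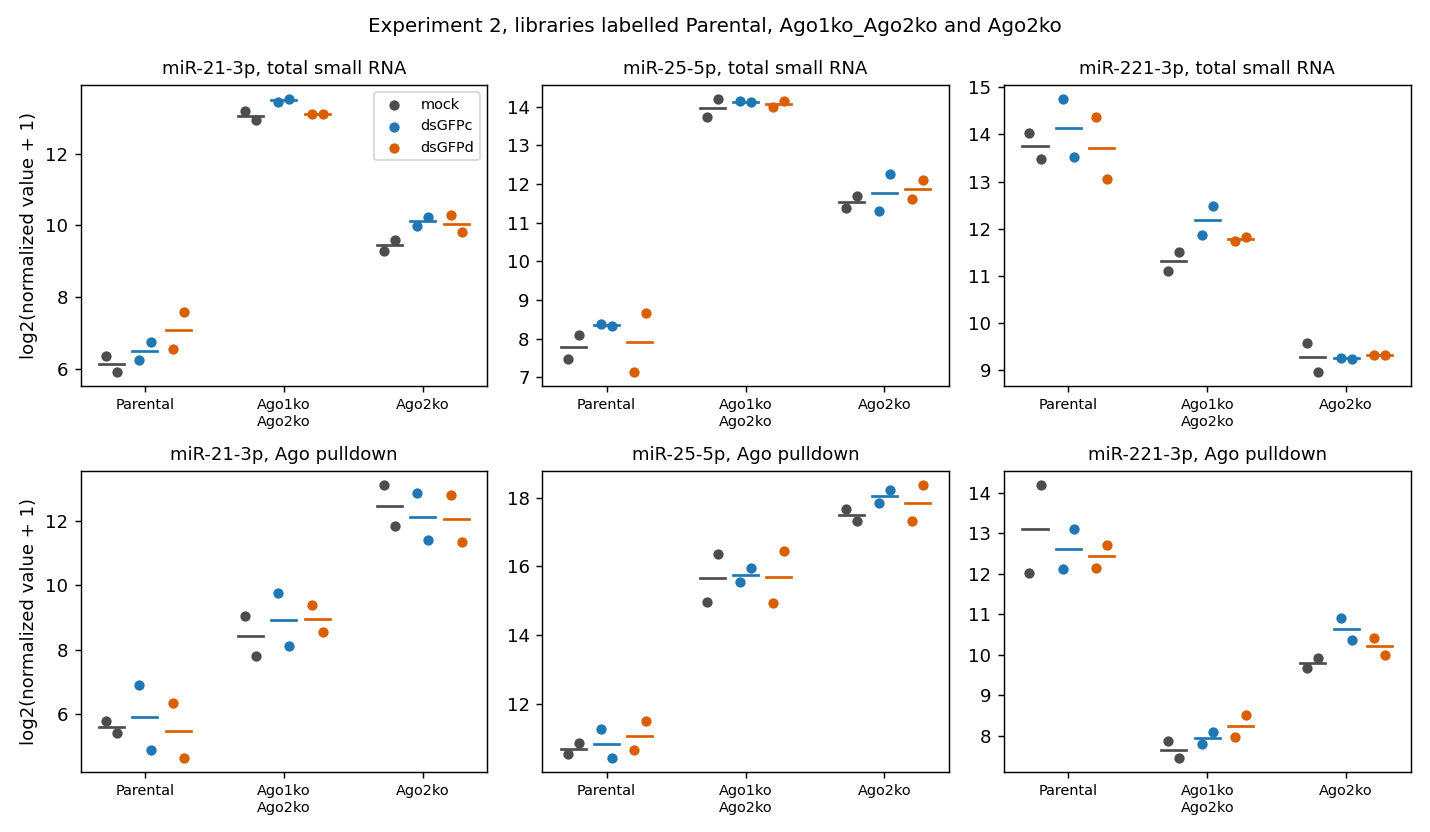
Level of miR-21-3p, miR-25-5p and miR-221-3p as log2(normalised value + 1) in experiment 2 libraries labelled Parental, Ago1ko_Ago2ko and Ago2ko, in total small RNA (top) and Ago pulldown (bottom), with a point per library and a bar at the mean of each group of 2. miR-21-3p averages 9649 in total libraries labelled Ago1ko_Ago2ko and 960 in those labelled Ago2ko, against 487 and 5358 in pulldown.

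Dicer knockout was compared with the parental line to ask which annotated miRNAs persist without the enzyme. On the deposited scaling most measured entries overlapping other small RNAs were higher in these shallow libraries. Whether their reads are fragments of those RNAs was not measured. In total RNA all 5 measured entries overlapping other small RNAs rose (5 adjusted over the list alone; limma camera adjusted p 5.85e-06, and 0.000638 with an estimated correlation). miR-1246 (MIR1246, chromosome 2, 176600980 to 176601052) rose from 2.82 ± 2.91 to 5039 ± 4145, or by 9.79, miR-3651 (within IARS1) by 7.31 and miR-7704 by 6.998. They were joined by miR-3609 (MIR3609, chromosome 7, 98881650 to 98881729, within TRRAP) at 8.81, miR-3613-5p at 8.27, miR-12136 at 7.05, miR-10395-5p at 6.82 and miR-10395-3p at 6.57, of which the last 3 became −0.14, −0.41 and −0.66 when the libraries were scaled on the entries overlapping other small RNAs. miR-29a-3p fell by 4.85, miR-193b-3p by 4.50, miR-185-5p by 4.37, miR-542-3p by 4.15, miR-652-3p by 4.004, miR-324-3p by 3.74, miR-3187-3p by 3.73, miR-330-3p by 3.66 and miR-598-3p by 3.64. miR-1301-3p had no read in any Dicer knockout library of total RNA. Its parental level of 30.01 ± 6.90 would give 13.03 reads over the 6 libraries, so on the deposited scaling it was at least 4.34-fold lower, counted against 3 reads over the group.

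Relative values of the abundant miRNAs depended on scaling in the Dicer knockout. miR-21-5p rose from 2589 ± 944 to 164100 ± 121800 and miR-16-5p by 1.40, but these became −1.91 and −5.83 when scaled on the overlapping entries and miR-16-5p −0.20 at the same sum. Of the 18 other abundant miRNAs 9 rose and 6 fell (median 0.53), against 4 and 9 at the same sum (−1.06), 5 and 9 after quantile normalization (−0.59) and 0 and 18 when scaled on those entries. In all 130 rose and 208 fell of 644 around a median of −0.77, with 68 and 302 at the same sum (−1.63) and 6 and 520 when scaled on those entries (−4.33). Markers of other cell types moved with this line, 3 up and 2 down around a median of −0.30, or 0.71 after quantile normalization. The liver marker miR-122-5p (MIR122, chromosome 18, 58451074 to 58451158, within MIR122HG) rose from a mean of 4.04 to 851 ± 740, miR-142-5p of blood cells by 4.69 and miR-143-3p of smooth muscle by 3.25, though the latter was −3.81 when scaled on those entries, and miR-200c-3p and miR-133a-3p fell. A read was worth 10.6 to 32.5 normalised counts in these Dicer knockout libraries and 0.145 to 0.323 in the parental ones. A few reads thus give a large value in the Dicer knockout. Whether these marker reads came from the line itself was not tested. The 5p to 3p ratio depends on scaling through the added 1 where an arm has few reads, and no other scaling was tried for it. It moved to 5p for 40 hairpins and to 3p for 11 of 153, with miR-25 at 4.04, miR-27b at 3.93, miR-423 at 3.47, miR-148a at 3.07 and miR-454 at 5.18, and miR-93 at −2.58, or −1.65 without Dicerko mock replicate 1. Part of this shift came with dsRNA. In mock libraries alone, tried after the values were seen, 12 hairpins were called toward 5p and 5 toward 3p, with miR-25 at 3.92, miR-27b at 4.45 and miR-454 at 5.78 but miR-423 at 1.295 and miR-148a at 1.17, the last not called. The ratios of miR-25 and miR-27b also rose in the libraries labelled Ago2ko (3.55 and 3.64) and Ago1ko_Ago2ko. Reads carried over from those libraries could thus move these 2 ratios in the same direction here, which was not tested for them. The 5p share in the summed Dicer knockout reads was 32.02% in mock and 85.7% with dsRNA for miR-423, and 17.1% and 56.3% for miR-148a. With a mean of at least 50 required of both arms the count of 51 was 22. Unchanged miRNAs made up 11.6% of the calls in the self-test of this comparison, in which 48% of 4-fold and 28% of 2-fold changes of 100 miRNAs each were recovered. For the arm ratio this share was 20%. The simulated changes were as often up as down, on the same mean levels in every line. These shares therefore do not cover errors that come from scaling.

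In Ago pulldown of the Dicer knockout 82 miRNAs rose and 302 fell of 762 around a median of −1.25, with 49 and 449 at the same sum (−2.01), 110 and 175 after quantile normalization (−0.10) and 13 and 586 when scaled on the overlapping entries (−3.34). Of those 5 entries 4 rose and 1 fell (4 and 1 adjusted over the list alone; limma camera adjusted p 0.00015, and 0.0030 with an estimated correlation), miR-1260b by 8.23, miR-1246 by 7.12 and miR-4286 by 4.86, with miR-664a-3p at −2.63. miR-21-5p rose from 2171 ± 498 to 154900 ± 131500, which became −0.0029 under that scaling, and miR-122-5p by 5.75. Among Dicer products 4 of 9 let-7 members fell, and of 7 mirtrons 5 fell (limma camera adjusted p 0.20). miR-6847-5p fell by 5.10, miR-577 by 4.81, miR-3605-5p by 4.54, miR-2116-3p by 4.51 and miR-222-5p by 4.44. miR-935, miR-1224-5p, miR-616-3p and miR-4741 had no read in the 6 libraries, against 38.9 ± 24.3, 24.6 ± 9.36, 24.9 ± 12.2 and 24.7 ± 10.2 in the parental line. These levels would give 25.3, 16, 16.2 and 16.1 reads over the 6 libraries, so on the deposited scaling the 4 were at least 8.44-, 5.33-, 5.41- and 5.36-fold lower against 3 reads over the group. The pulldown to total ratio was called for 2 up and 37 down of 900 (7 and 24 after quantile normalization), but 25 without parental dsGFPc total replicate 1 or parental mock pulldown replicate 2. Unchanged miRNAs made up 17.1% of the self-test calls in pulldown and 14.3% of those in this ratio, with the same limit of the simulation. Of the Dicer-independent list its only member, miR-451a, had too few reads to be tested in any comparison.

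Long dsRNA was compared with mock over the 4 lines of experiment 2. The ZC3HAV1-encoded miR-10399-3p rose by 5.83 in total RNA and 6.17 in pulldown. In total RNA 13 rose and 0 fell of 644 (by limma, 77 at an unadjusted p under 0.05 in both directions, with 11 lower by DESeq2 and 2 by edgeR, and 22 called without the Dicer knockout libraries), among them miR-664a-5p (4.17), miR-3609 (2.66), miR-20a-5p (2.17), miR-1246 (2.05) and miR-93-5p (1.43). The call of miR-181a-5p (1.37) was lost without Dicerko mock replicate 1 (adjusted p 0.051 by limma), and that of miR-34a-5p (2.23) without Dicerko mock replicate 2 (0.065) or Dicerko dsGFPd replicate 1 (0.055). Of 5 overlapping entries 2 rose (3 adjusted over the list alone; limma camera adjusted p 0.0132, and 0.0393 with an estimated correlation) and of the miR-17~92 clusters 2 of 10 (4 adjusted over the list alone; 0.0499, and 0.140). In pulldown 4 rose and 0 fell of 762 (by limma, 53 at an unadjusted p under 0.05 in both directions, with 0 lower by edgeR and by DESeq2), including miR-10399-5p (4.01) and miR-6891-5p (4.61), whose calls were each lost in 17 of the 24 fits without 1 library. The count of 4 was 2 without Dicerko mock replicate 1 or 2, parental mock replicate 2 or Ago2ko dsGFPd replicate 2, and 1 in 14 more of these fits. A response different from that of the parental line was called in the Dicer knockout, with 47 higher and 27 lower of 644 in total RNA and 21 and 6 of 762 in pulldown, by limma's interaction test. For miR-181b-5p the difference was 3.995 and 3.025 in the 2 fractions, for miR-20a-5p 4.21 and 6.03, for miR-182-5p 3.69 and 3.37 and for miR-21-5p 3.00 and 4.11. The scaling of that line moved with dsRNA. Its columns summed to 834345 to 1457522 in mock and 2055905 to 4038061 with dsRNA in total RNA. In pulldown the sums were 1024704 to 1035450 and 2381040 to 6070903. miR-182-5p took a large part of some of these pulldown libraries. No other scaling and no leaving out of libraries was tried for the interaction. In the libraries labelled Ago2ko and Ago1ko_Ago2ko limma called 0 in each fraction (12 and 14 at an unadjusted p under 0.05 in total RNA, 27 and 13 in pulldown), and edgeR and DESeq2 were not run for it. Whether their response differs from that of the Dicer knockout was not tested.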

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

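The interactions of cell line and fraction were planned, whereas those of dsRNA and cell line, the counts of splits and the tests of explanations were chosen after the results were seen, except that of arm changes with dsRNA in the other lines, which was written before its result.

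A difference between groups, tested as an interaction of cell line and fraction by limma, marked the pulldown to total ratio in the libraries labelled Ago2ko (9 miRNAs), in those labelled Ago1ko_Ago2ko (19) and in the Dicer knockout (39). A difference in the dsRNA response from the parental line, also tested as an interaction, marked the PACT and TRBP double knockout in pulldown (1 miRNA, miR-8072) and the Dicer knockout in total RNA (74) and pulldown (27). Of 100 splits of the libraries, the real one included, 3 gave as many as the 9 of Ago2ko (highest other 25), 5 as many as the 19 of Ago1ko_Ago2ko (highest other 55) and 12 as many as the 39 of Dicer (highest other 341). Labels were shuffled separately in each fraction, so a split can turn a difference between lines into a change of the ratio. The splits with 25, 55 and 341 calls may come from this. For these ratios the splits therefore do not decide whether chance gave the 9, 19 and 39 calls, and they were not corrected over the 34 comparisons. Neither splits nor other scalings were run for the dsRNA interactions.

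The differences between the 2 Ago knockout lines had opposite signs in total RNA and pulldown. Across 593 miRNAs, which are not independent replicates, their Pearson r was −0.76, whereas the same r for the double minus TRBP knockout difference of experiment 1 was 0.85 over 408. Low read counts as the whole cause are argued against by r of −0.97 over the 120 miRNAs with a mean of at least 1000 reads. An exchange of the 2 labels in 1 fraction is a candidate explanation, since the change from parental in total RNA had r of 0.86 and 0.77 with the other label in pulldown and 0.65 and 0.66 with its own. All 30 miRNAs called in both fractions had opposite signs. With the labels exchanged in pulldown, tried after the values were seen, limma called 0 and 1 miRNAs for the pulldown to total ratios in place of 9 and 19. This test recovered only 9 and 7% of 4-fold changes in the self-test. A different uptake by the pulldown in the 2 lines does not by itself predict opposite differences of like size. It cannot be excluded, because neither Ago mRNA nor protein is measured here.

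miRNA reads remained in the mock-transfected Dicer knockout libraries, with 39916 and 68253 reads in total RNA and 83321 and 47006 in pulldown. Reads carried over from other libraries may account for part of them, in which case their profile would resemble the sum of the other libraries of the fraction more than the parental line. In pulldown 36 of 39 miRNAs (92.3%) that differ over 2-fold between these lay closer to the sum. In total RNA 26 of 37 did (70.3%), between the 75% and 50% set as bounds, so carry-over cannot be told apart there from miRNAs of the line itself. Residual Dicer activity was not tested.

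Some arm ratios moved toward 5p with dsRNA in the Dicer knockout, 24 of 153 hairpins called in total RNA against 4 toward 3p (28 and 6 of 184 in pulldown, by limma), with a median log2 change over all 153 of 1.11. The mean of the medians of the other 3 lines was 0.0658, so a shift of the ratio of like size was not seen there. Those lines had at least 910155 reads per library in total RNA, against at most 180343 in the Dicer knockout. A like number of added 5p reads could be hidden among them, so a change that needs no Dicer loss is not excluded. Few reads in the mock libraries as the whole cause are argued against by a median of 2.27 (SE 0.56) over the 31 hairpins with a mean of at least 10 reads of each arm in them. This SE is over hairpins of the same libraries, which are not independent replicates, and does not measure the spread between libraries. Of the 24 called hairpins 21 had at least 10 reads in each of the 4 Dicer dsRNA libraries. Carry-over as the whole cause is argued against for 7 of these (miR-181a, miR-22, miR-423, miR-671, miR-151a, miR-501 and miR-361), in which each of the 4 libraries had a 5p share above every one of up to 84 libraries of other lines, by little for miR-22 (at least 1.29% against 1.22%). For the other hairpins it cannot be told apart. The 5p share in summed reads was tested for 105 hairpins against the highest of the 18 other total libraries (one-sided exact binomial test). At an adjusted p under 0.05, 17 of the 105 (16.2%) were above that share. This binomial test takes reads as independent and does not cover the spread between libraries. A response of the line to dsRNA remains a hypothesis that may explain the arm shift, found and tested on the same libraries.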

How the results depend on the processing

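The edgeR and DESeq2 fits on recovered reads, the fits with all loci, those without the Dicer libraries, those with exchanged Ago labels and those of arms in mock libraries alone were chosen after seeing the data, as were the counts of other splits. The planned comparisons of experiment 3 were not run, since no table of its own was at hand. The planned edgeR and DESeq2 settings were meant for counts and were run as added ones. Counts below are of called miRNAs (hairpins for arms), by limma unless another tool is named, beside the reported count in brackets. The cause of a change was not tested unless given.

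Requiring a log2 change of at least 1 lowers counts by construction. In experiment 1 total RNA it left 1 without PACT (6), 21 without TRBP (86), 10 without both (59), 34 between both and TRBP (151) and 11 with dsRNA (82). In pulldown it left 17 (36), 11 (21), 45 (96) and 36 (101) for the last 4, and 0 arms without TRBP and 0 without both (2 each, by limma, the tool run for arms, with 3 and 2 at an unadjusted p under 0.05).

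Mock libraries alone are fewer and gave fewer calls. In experiment 1 total RNA these were 1 for PACT (6), 17 for TRBP (86), 15 for both (59) and 53 for both against TRBP (151), and in pulldown 9 for TRBP (36), 5 for both (21) and 6 for both against TRBP (96). In experiment 2 total RNA they were 14 for Ago2ko (34), 72 for Ago1ko_Ago2ko (147), 152 for Dicer (338) and 23 between the Ago knockouts (66), and in pulldown 42 (183), 4 (21), 106 (384) and 4 (54). Mock arms were 0 for TRBP (2; 2 at an unadjusted p under 0.05 by limma, the tool run), 1 for both proteins (2), 4 for Ago2ko (10), 34 for Ago1ko_Ago2ko (63) and 17 for Dicer (51).

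With only the 2 lines compared the count was 5 for both proteins in pulldown (21) and 214 for Dicer in total RNA (338), but higher in total RNA for Ago2ko (113), Ago1ko_Ago2ko (255) and between them (224), and in pulldown for Ago1ko_Ago2ko (48) and between them (127). Without the shallow Dicer libraries these were 122, 288, 217, 53 and 162, dsRNA in total RNA of experiment 2 had 22 (13), the ratios of Ago2ko and Ago1ko_Ago2ko 100 (9) and 96 (19), and Ago2ko arms 59 (10). Part of the low counts of experiment 2 may thus come from the spread of the Dicer libraries.

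DESeq2 called more in pulldown for PACT, 3 (0), and for both proteins, 34 (21), 1 in the PACT ratio (0), and in experiment 2 total RNA 92 for Ago2ko (34), 247 for Ago1ko_Ago2ko (147), 155 between them (66) and 34 with dsRNA (13), in pulldown 37 for Ago1ko_Ago2ko (21) and 105 between them (54), and 55 and 63 in the ratios of Ago2ko and Ago1ko_Ago2ko. edgeR called 52 for Ago2ko in total RNA (34), 126 for pulldown against total RNA in experiment 2 (192) and 10 for the Dicer ratio (39). All loci gave 60 for that ratio. With the labels of the Ago knockouts exchanged in pulldown limma called 0 in the Ago2ko ratio (9; 18 at an unadjusted p under 0.05, 0 by edgeR and DESeq2) and 1 in that of Ago1ko_Ago2ko (19), miR-150-3p.

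Without a low-count filter more miRNAs are tested, and the counts were 2 for PACT (6), 39 for both proteins (59) and 53 with dsRNA (82) in total RNA of experiment 1, 11 for both in pulldown (21) and 1 with dsRNA in pulldown of experiment 2 (4). Quantile normalization gave 62 for Ago2ko (34) and 113 between the Ago knockouts (66) in total RNA, 101 between them in pulldown (54) and 21 for the Ago2ko ratio (9). The same sum gave 12 for Ago1ko_Ago2ko (21) and 101 between the Ago knockouts (54) in pulldown, 35 for the Ago2ko ratio (9) and 24 for that of Dicer (39). Scaling on overlapping entries gave 526 for Dicer in total RNA (338) and 599 in pulldown (384), since it lowers nearly all other miRNAs.

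A pseudocount of 10 gave 2 for the TRBP ratio (0), 110 between the Ago knockouts in total RNA (66), 24 and 36 for the ratios of Ago2ko (9) and Ago1ko_Ago2ko (19), and with dsRNA in experiment 2 4 in total RNA (13) and 1 in pulldown (4). A pseudocount of 0.1 gave 2 for the latter and 19 for the Dicer ratio (39), and 0.5 gave 0 arms for TRBP (2; 14 at an unadjusted p under 0.05 by limma, the tool run). A mean of at least 50 in both arms gave 4 arms for TRBP (2), 38 for Ago1ko_Ago2ko (63) and 22 for Dicer (51). Pulldown in place of total RNA gave 0 for TRBP and for both proteins (2 each; 19 and 16 at an unadjusted p under 0.05 by limma, the tool run), 48 for Ago2ko (10) and 3 for Ago1ko_Ago2ko (63).

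With replicate number as a replicate block the count for both proteins in pulldown of experiment 1 was 33, 9 up and 24 down (21), and each other count was within 1.5 times that reported. Whether the numbers pair libraries across groups was checked by correlating replicate differences between groups. In total RNA and pulldown of experiment 1 and then of experiment 2, 11, 21, 9 and 40 of 66 pairs of groups had r above 0.1, with medians of 0.02, 0.07, 0.03 and 0.16.

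Single libraries or a whole replicate number were left out in turn. In the latter case each group has a lone library, assumed to vary like the other groups. Counts in experiment 1 total RNA were 0 to 6 for PACT, 52 to 85 for TRBP, 24 to 64 for both, 86 to 144 for both against TRBP and 24 to 94 with dsRNA, and in pulldown 0 to 3, 7 to 57, 3 to 25, 33 to 88 and 11 to 125. Pulldown against total RNA had 109 to 351, the 3 ratios 0 to 0, 0 to 4 and 0 to 1, and the 3 arm comparisons 0 to 0, 0 to 2 and 0 to 3. In experiment 2 total RNA they were 15 to 39 for Ago2ko, 80 to 140 for Ago1ko_Ago2ko, 159 to 342 for Dicer, 17 to 59 between the Ago knockouts and 1 to 16 with dsRNA, and in pulldown 57 to 167, 6 to 22, 190 to 405, 5 to 49 and 1 to 6. Pulldown against total RNA had 106 to 191, the ratios 1 to 13, 5 to 18 and 20 to 48, and the arms 2 to 10, 29 to 66 and 17 to 59.

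Among named miRNAs the direction reversed as follows. In the Dicer knockout miR-16-5p became −0.20 in total RNA and −0.11 in pulldown at the same sum. Scaled on overlapping entries, in total RNA miR-21-5p became −1.91, miR-16-5p −5.83, miR-12136 −0.14, miR-10395-5p −0.41, miR-10395-3p −0.66 and miR-143-3p −3.81, and in pulldown miR-21-5p −0.0029, miR-16-5p −3.79 and miR-664a-5p −1.25, the last being −0.0425 in mock libraries alone. In the Dicer ratio edgeR gave 0.88 for miR-5701, 0.71 for miR-4458 and 0.18 for miR-7704, and DESeq2 0.67, 1.05 and 0.58 for these, 0.66 for miR-4483, 0.16 for miR-1268a and 0.0025 for miR-1268b. With libraries left out, 8019 values of named miRNAs kept their direction and side of the threshold, 888 lost a call and 14 gained one. With the Ago labels exchanged in pulldown the Ago2ko ratio became −0.19 for miR-21-3p, −0.41 for miR-92a-1-5p, −0.12 for miR-222-3p and −0.18 for miR-221-3p, and that of Ago1ko_Ago2ko −0.0922 for miR-148a-3p.

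Libraries of each comparison were also split at random into groups of the real sizes, 100 splits with the real one. Given as splits with as many calls, the real count and the highest other, experiment 1 total RNA had 1 (6, 5) for PACT, 1 (86, 40) for TRBP, 1 (59, 18) for both, 1 (151, 56) for both against TRBP and 1 (82, 12) with dsRNA. Pulldown had 100 (0, 12), 1 (36, 16), 3 (21, 58), 1 (96, 9) and 1 (101, 1). Pulldown against total RNA had 1 (363, 192), the ratios 100 (0, 7), 100 (0, 84) and 100 (0, 31), and the arms 100 (0, 2), 2 (2, 2) and 2 (2, 2). Experiment 2 total RNA had 1 (34, 7) for Ago2ko, 1 (147, 52) for Ago1ko_Ago2ko, 1 (338, 219) for Dicer, 1 (66, 3) between the Ago knockouts and 1 (13, 0) with dsRNA, and pulldown 1 (183, 39), 1 (21, 20), 1 (384, 166), 1 (54, 8) and 2 (4, 15). Pulldown against total RNA had 1 (192, 1) and the arms 1 (10, 2), 1 (63, 17) and 1 (51, 34). Where fewer than 5 splits did as well, a random assignment of single libraries seldom gave as many calls, at a share under 0.05. This share is not corrected over the 34 comparisons, for which 100 splits are too few. Chance differences between cultures are not excluded, since the labels do not say whether the 2 libraries of a group came from separate cultures. Where another split reached the real count (21, 4 and the arms with 2) the evidence from the splits is weak. A count of 0 is reached by every split, so there the test says nothing. Splits with 58 calls against 21 and 15 against 4, both within 1 fraction, point to a structure of the samples. Those with 84 and 31 against 0 are of ratios, for which labels were shuffled separately in each fraction. A split can there turn a difference between lines into a change of the ratio, so these 2 counts show no such structure.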

Other observations

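The tests of this part were written before their results, apart from the values of miRNAs already seen. A hypothesis that miRNAs within other interferon-stimulated genes rise with dsRNA could not be tested. Of 84 listed genes 4 span an annotated miRNA, which gives 8 mature names, and no member outside the genes already seen was measured. The 4 measured miRNAs of the genes already seen had a median log2 change of 5.12 in pulldown of experiment 1, with 4 of 4 called, and 4.31 in experiment 2, with 3 of 4 called, both at percentile 100 of 10000 random sets, which is no independent test since they were chosen for this change.

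A single miRNA took a large part of some libraries. miR-182-5p made up 56.7% of the reads of the Dicer knockout pulldown library dsGFPc replicate 2 and 52.1% of dsGFPd replicate 2. In total RNA of that line miR-20a-5p was at 1757 and 2902 in the mock libraries, 84720 and 55120 with dsGFPc and 143000 and 299500 with dsGFPd.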
